A study of Mus musculus with 11 samples.

How the data were processed

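The study measured messenger RNA in whole brains of 11 mice, 1 array per mouse. The labels describe 5 mice as homozygous null for the β4 subunit of the nicotinic acetylcholine receptor, encoded by Chrnb4, and 6 as wild-type littermates, all of strain C57BL/6J and 6 to 9 weeks old. The nicotinic receptor is an ion channel gated by acetylcholine, and each receptor is built of 5 subunits. Per the labels' protocols, total RNA was taken from each brain with TRI Reagent, cleaned on a spin column and labelled with biotin through an Enzo transcript labelling kit.

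The deposited values are one intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. MAS5 combines the probes of a probe set into 1 signal and scales each array to a common mean. The version, the background settings and the array scanner were not given in the sources used here, and no detection calls were used. In the deposited intensity table the mean after trimming 2% at each end was 150.1 on every array, so the arrays were used as scaled. Each array holds 12488 probe sets, of which 66 are controls and were left out of the tests. The table pairing probe sets with genes gave 1 gene for 10855, several for 396 and none for 1237. Only probe sets with 1 gene were named, and 10839 of them matched the reference gene table of assembly GRCm38.p6, which was used for chromosomes and the order of neighbouring genes. No probe set is named for Chrnb4, Chrna3, Chrna4 or Chrna5 there, so the disrupted gene has no value and could not be used to check the genotype labels.

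The groups, comparisons, gene lists, tests, naming rule and most alternatives were fixed before the data were examined. Intensities under the 10th percentile of the whole table (a signal of 3.1) were raised to it and log2 values were taken. Probe sets whose mean log2 signal lay under the 40th percentile (4.69, a signal of 25.8) were not tested. That left 7453 probe sets of 5699 named genes and of unnamed probe sets. Only 6 of all values were 0. Between 7.73% and 11.8% of the values of an array lay at the floor, and the number of arrays sets the precision of every value. Levels are given as mean ± SD of the linear signal and fold changes as log2 differences with their standard error (SE), so a fold is understated where a signal is near the floor.

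limma 3.58.1 in R 4.3.3 was used for all tests across probe sets (lmFit, then eBayes with a trend of variance on signal, Benjamini-Hochberg adjustment, adjusted p threshold 0.05). The genotype difference is null minus wild-type with sex as a covariate, because 4 of 6 wild-type and 2 of 5 null mice are male. The sex difference is female minus male with genotype as a covariate. A further model holds the interaction of genotype and sex. Its value is the genotype difference in females minus that in males, and the difference within each sex comes from the same model. Single quantities per array were compared with two-sided exact permutation tests of log2 values, except the median signal, which was compared unlogged.

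For each comparison the rule names all probe sets past the threshold if they number 30 or fewer, otherwise the 15 largest rises and the 15 largest falls. Where fewer than 20 pass, the next by p fill the number up to 20 and are named as not past the threshold. Nicotinic subunits, genes of the sex chromosomes and list members that pass when adjusted over the list alone are always named. 33 lists were written (receptors, synapse, cell types, brain regions, stress, organelles and the neighbours of Chrnb4), and the genes within 100 positions of Chrnb4 on its chromosome made a further one. Of these, 28 had at least 5 tested members. The other 6, which are erythroid cells, medial habenula, pineal gland and retina, cholinergic neurons, nicotinic subunits and sex chromosome dosage, were too small to test as lists. Each gene entered a list through its brightest probe set. Lists were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation and with fry. Genes near Chrnb4 were counted with two-sided Fisher's exact tests.

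The scripts were tested on simulated data made from the real means and spread of 7453 probe sets. With 200 probe sets changed, the genotype test recovered 67% of 2-fold and 97% of 4-fold changes, with 5 false calls among 169, and made 0 calls with no change. The interaction test recovered 18% and 73%, with 8 false calls among 99, and 0 with no change. A shift of 0.5 log2 put into the proteasome list was called, 0 of the other lists were, and 0 were called with no shift. Genes varied independently in these simulations, so they could not show false list calls that arise from correlation between genes. No simulated array stood apart from the rest, unlike the male null arrays described below. The counts of false calls therefore do not cover calls that arise from such arrays.

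The alternatives were quantile normalization, centring on each array's median, other floors and filters, other covariates, the letters of the animal numbers (B4 or LT) as a block, subsets of animals, equal variance over signal, array weights, an adjusted p of 0.10 and leaving out each mouse in turn. The wild-type mice comprise 3 with B4 and 3 with LT numbers, while all 5 null mice have B4 numbers. After the data were seen, 6 alternatives were added: leaving out the 2 male null arrays, the same within B4 animals, the Gapdh 5′/3′ control ratio as a covariate, B4 animals alone for the sex and interaction terms, the lists on the interaction and within each sex, and the lists after median centring. Replicate numbers follow the order of deposition and only name a mouse, so they pair no mice across groups.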

Results

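Whole brains of 11 adult mice were profiled, 6 wild-type (4 male, 2 female) and 5 null for the β4 nicotinic receptor subunit (2 male, 3 female), to compare gene expression between mutants and littermate controls. All arrays had the same trimmed mean signal of 150.1, and their median signals lay between 43.6 and 58.3. The median signal was 50.8 ± 5.96 (SD, n = 5) in null and 46.3 ± 2.63 (SD, n = 6) in wild-type brains (exact permutation p = 0.141). It was 58.3 and 56.3 in the 2 male null brains and 43.6 to 49.75 in all others.

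The control probe sets for Gapdh, a glycolytic enzyme measured at both ends of its transcript, differed between the genotypes. The ratio of 3′ to 5′ Gapdh signal was 4.24 ± 0.862 (SD, n = 6) in wild-type and 2.04 ± 1.21 (SD, n = 5) in null brains (exact permutation p = 0.00433). It was 0.859 and 0.798 in the 2 male null brains, 2.75, 2.20 and 3.58 in the 3 female null brains, and 3.57 to 5.92 in the wild-type brains. The first principal component held 39.7% of the variance. It placed the male null brains at 47.3 and 49.2 and the other 9 between -16.3 and -2.03. Pairs of arrays correlated at 0.863 to 0.969 across probe sets, and the highest value was that of the 2 male null brains. Another control ratio, that of the spiked-in bacterial transcripts BioB and BioC, followed the animal numbers: 0.617 ± 0.0292 (SD, n = 3) with LT numbers and 0.257 ± 0.0388 (SD, n = 8) with B4 numbers (exact permutation p = 0.00606). Among wild-type brains the Gapdh ratio was 4.43 ± 1.29 (SD, n = 3) with LT and 4.04 ± 0.265 (SD, n = 3) with B4 numbers (exact permutation p = 1, with 0.1 the smallest that 3 against 3 can give).

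**Figure D1:**
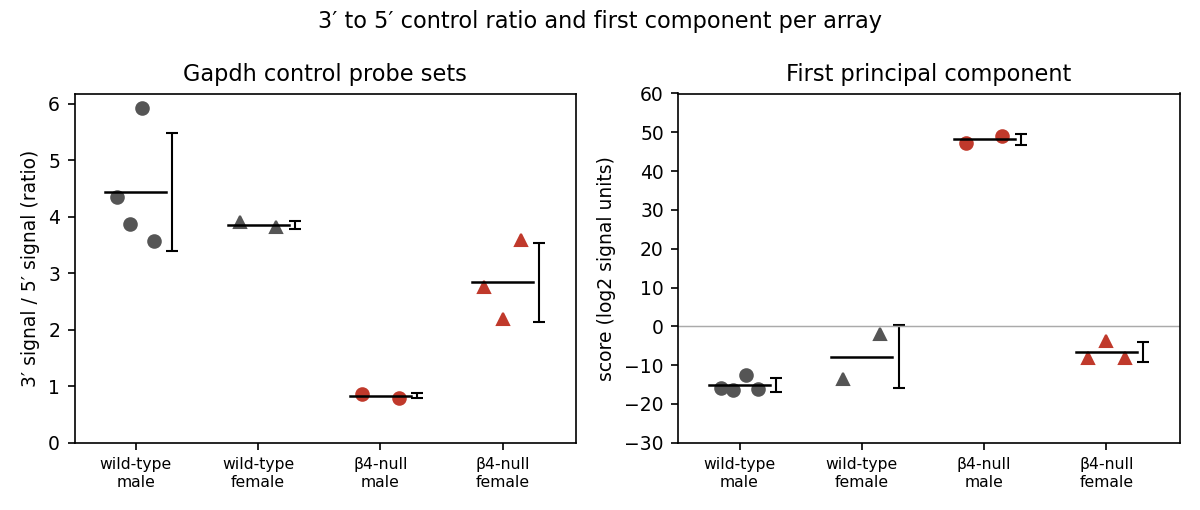
Ratio of 3′ to 5′ Gapdh control signal (left) and score on the first principal component of the log2 signals (right) for each array, by genotype and sex; lines are means and bars SD. The 2 male null arrays have ratios of 0.859 and 0.798 and scores of 47.3 and 49.2, apart from the other 9 arrays on both measures.

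Spg21, which encodes maspardin, the protein affected in the hereditary spastic paraplegia called Mast syndrome, fell in null brains. Its probe set 95430_f_at had a signal of 420.6 ± 109.9 (SD, n = 6) in wild-type and 72.9 ± 23.7 (SD, n = 5) in null brains, 5.89-fold lower in the log2 model with sex. Every null brain (5 of 5) lay below all wild-type brains. The log2 difference was -2.56 (SE 0.27, limma adjusted p = 0.0017). Spg21 lies on chromosome 9, 123 protein-coding genes from Chrnb4. Pycrl (160197_at, chromosome 15), a pyrroline-5-carboxylate reductase of proline synthesis, rose from 36.7 ± 12.5 (SD, n = 6) to 81.8 ± 22.5 (SD, n = 5), with 5 of 5 null brains above all wild-type brains. In the log2 model with sex the rise was 2.68-fold. Its log2 difference was 1.42 (SE 0.21, limma adjusted p = 0.0414). These were the only 2 of 7453 probe sets past the threshold, 1 higher and 1 lower in null brains; 1724 had an unadjusted p under 0.05, 1002 higher and 722 lower. The suffix of the Spg21 probe set marks probes that can also bind related sequences.

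The Spg21 difference was -3.28 in males and -1.76 in females, and these differed from each other (interaction 1.52, limma adjusted p = 0.0107). The female wild-type brains were wild-type 3 and wild-type 5, at Spg21 signals of 211.6 and 426.8. Wild-type 3 lay below all other wild-type brains, so part of the interaction rests on that brain. For Pycrl the male and female differences were 1.30 and 1.56. Within B4 animals, which include 3 wild-type brains, the differences were -2.43 for Spg21 and 1.48 for Pycrl (limma adjusted p = 0.0204 and 0.0337) and 26 probe sets passed, 24 of them higher. LT numbers hold wild-type brains only. With the number letters as a block 3 passed: Spg21 again (-2.41, limma adjusted p = 0.0384), Sult4a1 and, named only after its value was seen, Gnaz, while Pycrl had an adjusted p of 0.0776. The Spg21 probe set kept its call without each mouse in turn, but not with age as a covariate (-2.44, adjusted p = 0.11) or without the signal filter (-2.56, adjusted p = 0.0793). With 1 mouse left out, Pycrl kept its call only without wild-type 3, wild-type 5 or null 5. It also lost it with age (adjusted p = 0.375), without the filter (0.095), after quantile normalization (0.096), after median centring (0.0562) and without a covariate (0.255). The count was 877 without wild-type 5, 195 without wild-type 3, 9 without null 5 and 1 without any other mouse. Without the 2 male null brains 0 passed (limma; 264 at an unadjusted p under 0.05), and the log2 differences were -1.76 for Spg21 (adjusted p = 0.116) and 1.56 for Pycrl (adjusted p = 0.647). With the Gapdh 5′/3′ ratio as a covariate 0 passed (limma; 347 at an unadjusted p under 0.05), and the differences were -1.58 for Spg21 (SE 0.32) and 1.66 for Pycrl (SE 0.35), each with an adjusted p of 0.994.

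**Figure D2:**
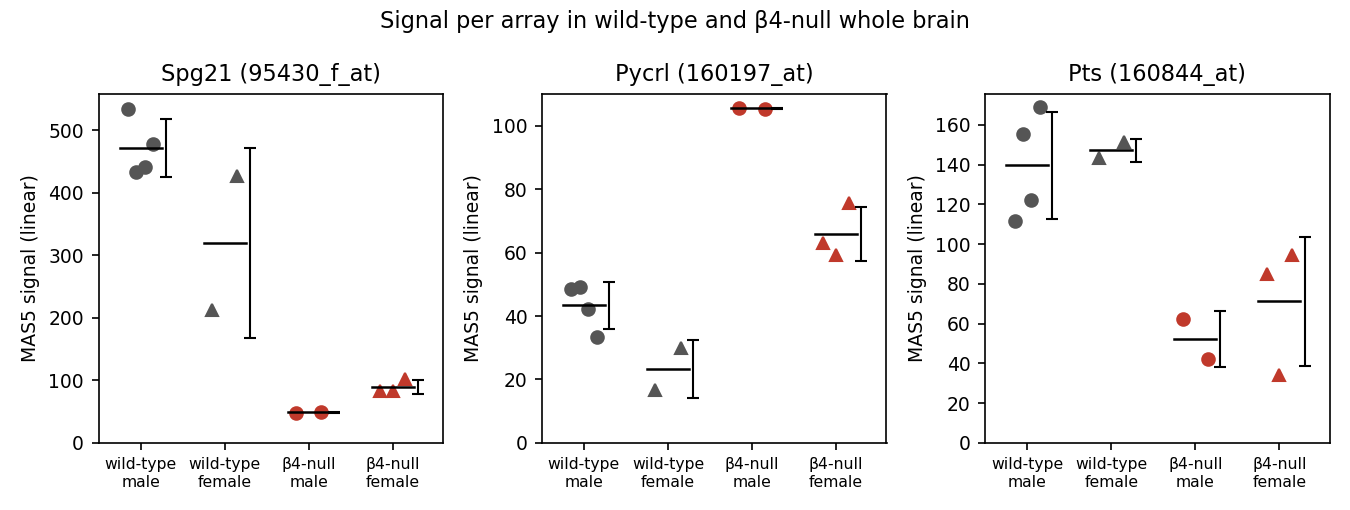
MAS5 signal (linear) of Spg21, Pycrl and Pts in each brain, by genotype and sex; lines are means and bars SD. All 5 null brains lie below the 6 wild-type brains for Spg21 and Pts and above them for Pycrl; Pts did not pass the threshold over all genes.

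The next 18 probe sets by p did not pass (limma adjusted p = 0.0773 for each), and 14 of them had higher means in null brains. The synaptic vesicle calcium sensor Syt1 had a signal of 208.6 ± 47.1 (SD, n = 6) in wild-type and 770.1 ± 612 (SD, n = 5) in null brains (1.82 log2). The brain sulfotransferase Sult4a1 had 80.9 ± 30.8 (SD, n = 6) and 278.8 ± 233 (SD, n = 5; 1.93). The lipid transporter Abca2 had 194.1 ± 21.96 (SD, n = 6) and 379.8 ± 140 (SD, n = 5; 1.01). The other positive log2 differences were 2.12 for Sema7a, 1.94 for the kinesin Kif5c, 1.72 for the ephrin receptor Epha4, 1.59 for the sorting nexin Snx2, 1.26 for the transferrin receptor Tfrc, 1.19 for Rasgrp1, 1.07 for the semaphorin receptor Plxnb2, 0.997 for the G protein subunit Gnao1, 0.97 for the ribosome assembly factor Nsa2, 0.93 for the unnamed 102163_at and 0.87 for the growth factor Fgf1. The negative ones were -1.75 for the kinase Mapk7, -1.31 for Pts, an enzyme of tetrahydrobiopterin synthesis, -0.96 for the small heat-shock protein Cryab and -0.88 for S100a13. The differences were 2.74 in males and 0.79 in females for Syt1, and 2.58 and 0.49 for Snx2. For Pts the male and female differences were -1.42 and -1.18, and for Cryab -1.21 and -0.67. All the differences over both sexes in this paragraph include the male null brains, whose arrays stood apart. Without those brains no gene passed over all genes. For several of these genes a brighter probe set gave another value: 0.04 for Plxnb2, -0.23 for Sema7a, 0.09 for Snx2, -0.46 for Gnao1 and -0.30 for S100a13.

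None of 28 gene lists passed for genotype with camera at the preset correlation, with the estimated correlation or with fry, and 0 list members passed over all genes. The list of synaptic vesicle and release genes had 20 members with a median log2 difference of 0.42 (camera adjusted p = 0.175; with an estimated correlation adjusted p = 0.874). Adjusted over the list alone, 9 passed higher, which were Vamp1 (2.68), Syt11 (1.92), Syt1 (1.82), Cplx1 (0.99), Nsf (0.92), Syp (0.90), Stx1a (0.61), Napb (0.56) and Syt3 (0.51), and Dnm1 passed lower (-0.54). Cplx1 was 0.59 without null 2 and Nsf 0.60 without null 1. Quantile normalization took this list past the threshold (adjusted p = 0.00942), as did median centring (adjusted p = 0.0404). The 36 members of the mitochondrial respiratory chain had a median of -0.24 (adjusted p = 0.175), from Ndufa5 at -0.67 to Ndufv1 at 0.76, and 0 passed adjusted over the list alone. This list passed within B4 animals (adjusted p = 0.0105, median -0.30), with the number letters as a block (adjusted p = 0.00782), with age as a covariate (adjusted p = 0.0285) and without wild-type 5 (adjusted p = 0.019). With the estimated correlation none of these calls held under the same alternatives, the lowest adjusted p being 0.874. Without the male null brains, whose Gapdh control ratios were 0.859 and 0.798, 0 lists passed, and none of the named synaptic genes passed adjusted over the list alone (lowest adjusted p = 0.303, for Syt1). The differences were then -0.01 for Vamp1, 0.43 for Syt11, 0.79 for Syt1, -0.29 for Cplx1, 0.0028 for Nsf, 0.0085 for Syp and 0.04 for Stx1a.

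Among transmitter systems, GABA receptors and synthesis (7 genes, median 0.21) had Gabra2 (1.64) and Gabrd (0.64) higher and the vesicular transporter Slc32a1 (-0.72) and Gabrb1 (-0.34) lower adjusted over the list alone. Of 9 glutamate receptors and transporters (median 0.31), Gria1 (0.93) and Slc1a1 (0.77) passed so. Of 12 monoamine genes (median 0.34, adjusted p = 0.32), 19 neuropeptides and opioid receptors (median -0.10, mean 0.01), 21 calcium and calmodulin genes (median -0.03) and 12 postsynaptic density genes (median -0.01), 0 passed so. Their extremes were Htr5b (0.68) and Htr3a (-0.80), Trh (1.40) and Pomc (-0.57), Atp2b2 (0.96) and Nrgn (-0.77), and Dlg4 (0.63) and Cntn1 (-0.23). Immediate-early genes (19, median 0.09) had Junb (0.65) and Dusp6 (0.46) higher and Jund (-0.54) lower. Except for monoamines, adjusted p was 0.82 for each of these lists. Without the male null brains none of these genes passed for genotype adjusted over the list alone (lowest adjusted p = 0.513, for Gria1), with Gabra2 at 0.89, Gabrd at 0.17, Slc32a1 at -0.31 and Slc1a1 at 0.13.

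No cell type or region list passed. The medians were 0.22 for oligodendrocytes (9 genes, with Mobp at -0.50 past the list-alone threshold), -0.04 for astrocytes (13, with the glutamine synthetase Glul at 0.80 past it), 0.33 for microglia (10), -0.01 for endothelium and mural cells (15, with Eng at -0.69 past it), -0.19 for choroid plexus (7) and 0.21 for pituitary (5, mean -0.07). Regional lists gave -0.08 for cerebellum (11, adjusted p = 0.447), -0.32 for cortex and hippocampus (7, adjusted p = 0.569; Nptx1 at 0.82 and Tbr1 at -0.70 passed over the list alone), -0.14 for striatum (6), 0.08 for hypothalamus (7, Trh at 1.40 passed) and 0.24 for olfactory bulb (6). The medians of housekeeping and stress lists were 0.09 for major histocompatibility and interferon genes (12), -0.01 for the proteasome (28, mean 0.09; Psmc5 at 0.75 passed), -0.15 for heat shock and unfolded protein genes (21; Atf4 at 0.45 and Cryab at -0.96 passed), 0.04 for ribosomal proteins (13), 0.12 for the circadian clock (12; Cry2 at 1.26, Dbp at -1.04 and Cry1 at -0.47 passed) and 0.09 for cell division (11). Where no adjusted p is given it was 0.82. Ribosomal proteins passed upward after quantile normalization alone (camera adjusted p = 0.0373), a call that did not hold with the estimated correlation. None of the genes named from these lists passed over the list alone without the male null brains (lowest adjusted p = 0.261, for Mobp), where Nptx1 stood at 0.11, Dbp at -0.31, Psmc5 at 0.23 and Glul at 0.69.

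A null allele made by gene targeting can carry DNA of another strain beside the disrupted gene, so the neighbours of Chrnb4 were counted. Of 63 tested genes within 100 positions on either side, 0 were called by limma (odds ratio 0, exact Fisher p = 1), with 13 at an unadjusted p under 0.05, or 20.6% against 22.8% of other genes (exact Fisher p = 0.764). Adjusted over the list alone, Neo1 (0.96), a receptor of axon guidance, passed higher and Pts (-1.31), Cryab (-0.96), Adpgk (-0.85) and Dlat (-0.59), a subunit of pyruvate dehydrogenase, passed lower. Pts had a signal of 142.2 ± 21.5 (SD, n = 6) in wild-type and 63.6 ± 26.1 (SD, n = 5) in null brains. Dlat had 189.4 ± 30.5 (SD, n = 6) and 126.8 ± 6.93 (SD, n = 5), and all 5 null brains were below all wild-type brains for both genes. As a list these 63 genes had a median of -0.01 (camera adjusted p = 0.565), and the 36 neighbours named beforehand a median of 0.01 and a mean of -0.04 (adjusted p = 0.82; 1 higher and 3 lower over the list alone). None did so without the male null brains (lowest adjusted p = 0.105, for Dlat). In the 9 brains without the male null brains, where with sex in the model the genotype difference rests on 3 null against 2 wild-type females, 1 of these with an LT number, 8 of the 63 genes (12.7%) had an unadjusted p under 0.05 against 3.46% of other genes (exact Fisher p = 0.00162). Closer to Chrnb4 there was no such excess: 0 of 12 genes within 25 positions had such a p by limma, and 1 of 26 within 50, or 3.85% against 3.56% (exact Fisher p = 0.611). Spg21 lies just outside that window; counting 250 genes on each side put it inside, with an odds ratio of 41.8 (exact Fisher p = 0.0465). The odds ratio was 3.43 without wild-type 3 (exact Fisher p = 0.012) and 1.39 without wild-type 5.

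**Figure D3:**
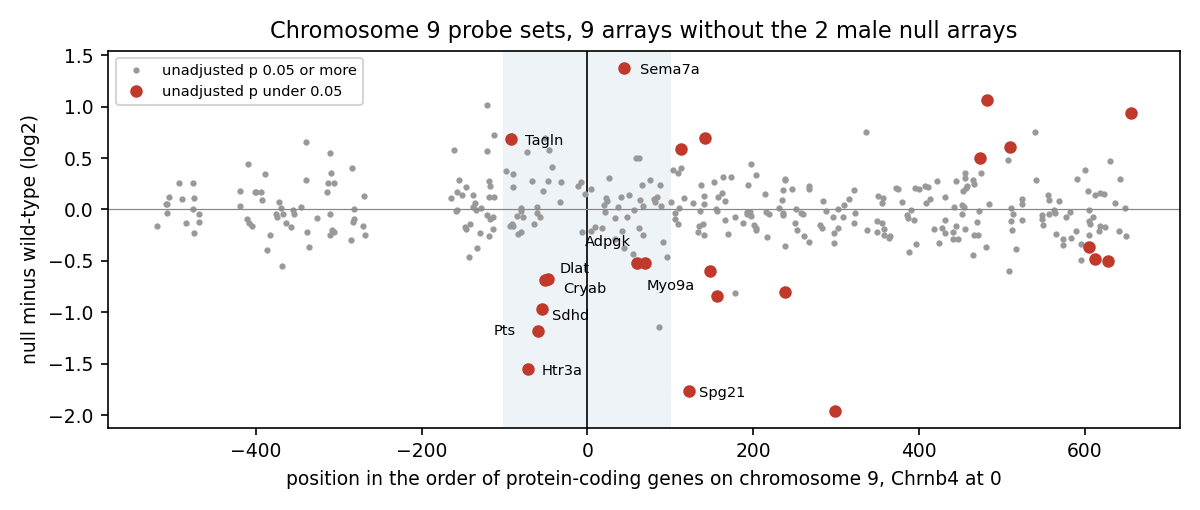
Null minus wild-type log2 difference of each tested chromosome 9 probe set in the 9 brains without the male null brains, in the order of protein-coding genes with Chrnb4 at 0; shading marks 100 genes on each side and red marks an unadjusted p under 0.05. Within the shaded part 8 of 63 genes (12.7%) reached that level through their brightest probe set; Sema7a, at 1.38, is shown through a dimmer probe set and is not among them.

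Of the nicotinic receptor subunits other than β4, none passed for genotype. Chrna7, the α7 subunit, had a signal of 62.2 ± 17.7 (SD, n = 6) in wild-type and 61.4 ± 22.7 (SD, n = 5) in null brains (0.12 log2; the sign turned under both other scalings). Chrnb2, the β2 subunit, was under the signal filter at 13.8 ± 7.51 (SD, n = 6) and 13.4 ± 3.21 (SD, n = 5). Chrng had -1.69 (SE 0.43, limma adjusted p = 0.19) through 95639_at and 1.47 through the dimmer 161215_at, so its probe sets disagreed. The log2 differences of the rest were 0.97 for Chrne (92967_r_at, limma adjusted p = 0.234), 0.97 for Chrna1, -0.08 for Chrna6, -0.41 for Chrnb1 and -0.44 for Chrnd. With 1 mouse left out these moved by over 1.5 times for some, as for Chrnd (-0.77 to -0.06) and Chrna1 (0.62 to 1.33). The 2 other Chrne probe sets gave 0.63 and -0.09, and only Chrna7, 92967_r_at and 95639_at passed the signal filter.

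The Y chromosome genes Eif2s3y and Uty matched the sex labels. Eif2s3y, a translation initiation factor subunit, had a signal of 89.8 ± 23.8 (SD, n = 6) in male and 4.98 ± 3.59 (SD, n = 5) in female brains, and the histone demethylase Uty 28.7 ± 9.22 (SD, n = 6) and 3.22 ± 1.86 (SD, n = 5). All 6 male brains lay above all female brains for both genes. Xist, the RNA that silences an X chromosome in females, had 8.43 ± 6.90 (SD, n = 6) and 52.5 ± 30.1 (SD, n = 5). Its difference was 2.44 log2 (limma adjusted p = 0.341). Xist did not fully separate the sexes, since null 3, a female, at 9.9 lay below the males wild-type 1 (14.7) and null 1 (18.1). All of these genes lay under the signal filter. Without the filter 3 probe sets passed, all lower in females: 103842_at (-5.50), which has no gene name and was singled out after its value was seen, Eif2s3y (-4.08, limma adjusted p = 0.00479) and Uty (-3.004, limma adjusted p = 0.0139). Eif2s3x was 955 ± 95.7 (SD, n = 6) in males and 1218 ± 213 (SD, n = 5) in females (0.35, limma adjusted p = 0.41). Kdm6a had 0.18. Kdm5d, also on the Y chromosome, lay near the floor and did not separate the sexes, at 6.22 ± 4.03 (SD, n = 6) in males and 4.34 ± 1.85 (SD, n = 5) in females (-0.53; 0.34 without the male null brains), and the probe sets of Ddx3x -0.07, -0.23 and -0.37.

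**Figure D4:**
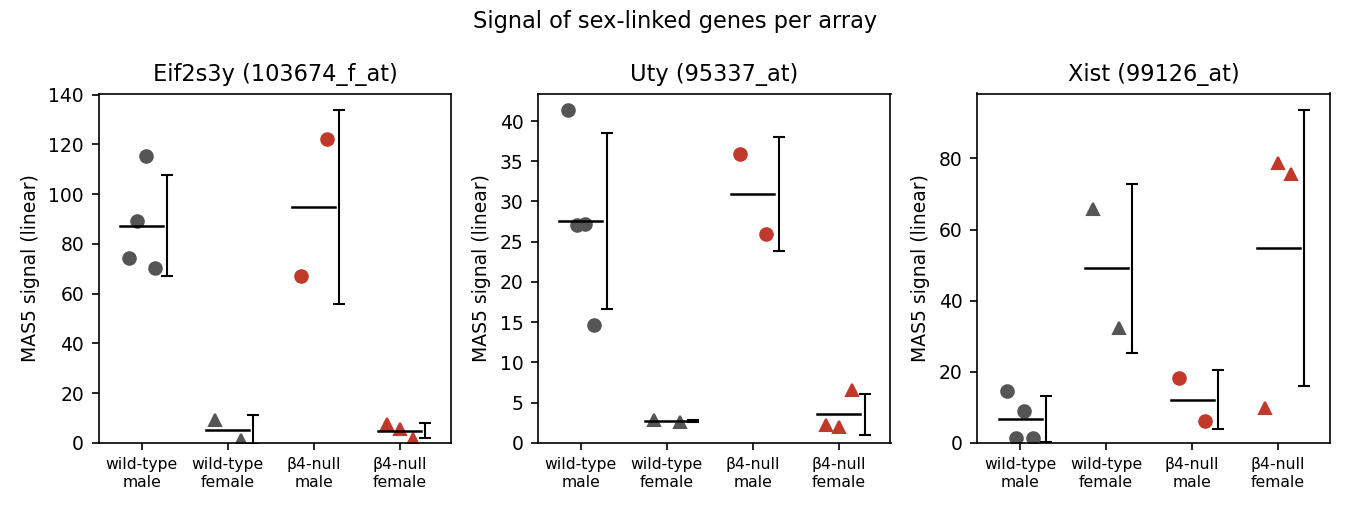
MAS5 signal (linear) of Eif2s3y, Uty and Xist in each brain, by genotype and sex; lines are means and bars SD. All 6 male brains lie above all 5 female brains for Eif2s3y and Uty. For Xist null 3, a female, has a signal of 9.9, below the males wild-type 1 (14.7) and null 1 (18.1).

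With the signal filter, 0 of 7453 probe sets passed for sex (limma; 926 at an unadjusted p under 0.05, 364 higher and 562 lower in females). The first 20 by p did not pass (limma adjusted p = 0.261 for each). The neuropeptide Avp, vasopressin, had a signal of 310.7 ± 114.5 (SD, n = 6) in male and 134.6 ± 44.5 (SD, n = 5) in female brains (-1.29 log2). It passed adjusted over the list alone among neuropeptides (adjusted p = 0.014) and hypothalamic genes (adjusted p = 0.00516), and Npy (0.44) did among neuropeptides (adjusted p = 0.0472). Without the male null brains the sex differences were -1.11 for Avp and 0.24 for Npy. Cdc42se2 was the only gene of the 20 with a higher mean in females, 449.4 ± 65.8 (SD, n = 6) in males and 636.5 ± 86.9 (SD, n = 5) in females (0.58). The log2 differences of the others were -1.96 for 95907_at, -1.69 for the kinesin Kif5a, -1.57 for Auh, -1.54 for the transcription factor Junb through 102362_i_at, -1.52 for Ywhag, -1.50 for Bag6, -1.46 for 92659_at, -1.45 for Sult4a1, -1.43 for Cand1, -1.36 for Rasgrp1, -1.36 for Cdk5r1, -1.29 for Myo10, -1.23 for Vps51, -1.18 for the clock-related factor Nfil3, -1.06 for 95801_s_at, -0.96 for Csnk1d, -0.81 for Plxnb2 and -0.75 for Anxa7. Within B4 animals 10 probe sets passed, all lower in females. LT numbers hold wild-type brains only, 1 of them female, and with the number letters as a block 0 passed. Without wild-type 5, a female, 30 passed.

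As lists, immediate-early genes were lower in females (19 genes, median -0.36, camera adjusted p = 0.00789) and mitochondrial respiratory chain genes higher (36 genes, median 0.19, camera adjusted p = 0.000915). With an estimated correlation each had an adjusted p of 0.606, and fry called 0. Among immediate-early genes the differences ran from -0.72 for Junb, through its brightest probe set 102363_r_at, to 0.53 for Sgk1, and among respiratory chain genes from -0.27 for Ndufv1 to 0.41 for Atp5c1. None passed singly, over all genes or adjusted over the list alone. Without the male null brains, with their low Gapdh control ratios, 0 lists passed. Within B4 animals the respiratory chain passed (adjusted p = 0.00106) and immediate-early genes did not. The respiratory chain also lost its call after quantile normalization (adjusted p = 0.282), and immediate-early genes lost theirs without wild-type 5. The other 26 lists did not pass, though some did under an alternative: synaptic vesicle genes lower in females after quantile normalization (adjusted p = 0.00291), after median centring (adjusted p = 0.0453) and without wild-type 3 (adjusted p = 0.0276), cerebellum genes higher within B4 animals (adjusted p = 0.0285), ribosomal proteins higher with age (adjusted p = 0.00215) and without wild-type 2 (adjusted p = 0.0495), and olfactory bulb genes higher with age (adjusted p = 0.0391). With the estimated correlation none of these calls held.

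The genotype difference was not the same in males and females. The male difference rests on 2 null brains, those with the lowest Gapdh 3′/5′ ratios, so sex and these arrays cannot be told apart. In males Gnb1, a G protein β subunit, fell from 1161.7 ± 179 (SD, n = 4) to 228.1 ± 1.41 (SD, n = 2) and Dio2, the deiodinase that activates thyroid hormone, from 557.9 ± 167 (SD, n = 4) to 104.3 ± 7.71 (SD, n = 2). The male log2 differences were -2.34 and -2.36 and the female ones -0.26 and -0.50. Rangap1, the activator of the nuclear transport GTPase Ran, rose in males from 21.5 ± 7.38 (SD, n = 4) to 440 ± 56.1 (SD, n = 2), and the vesicle protein Vamp1 from 22.1 ± 19.3 (SD, n = 4) to 543.5 ± 124 (SD, n = 2). Their differences were 4.41 and 5.10 in males against 0.02 and -0.01 in females. The interaction passed for 1187 probe sets, 540 positive and 647 negative (limma, 2304 at an unadjusted p under 0.05). Among the 1187, 1151 also passed in males.

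In males 2433 probe sets passed, 1330 higher and 1103 lower in null brains; in females 0 did (limma, 308 at an unadjusted p under 0.05). Across probe sets, which are not independent replicates, male and female differences correlated at r = 0.0216 (rho = -0.0108), with SDs of 0.73 and 0.32. Within B4 animals the interaction passed for 644 probe sets, 284 positive and 360 negative, and with the number letters as a block for 1582. With the Gapdh 5′/3′ ratio as a covariate 0 interactions passed by limma. In a separate model of genotype, sex and the ratio, without the interaction, the ratio passed for 588. There the ratio can stand in for the male null brains. The male null brains are also those with Gapdh ratios of 0.859 and 0.798. The count was 461 without null 2, 650 without null 1 and 499 without wild-type 5.

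The 15 largest positive interactions, where the female difference lay above the male one, were Itgav (3.21), Klk6 (2.70), Mvk (2.64), Abcc3 (2.55), Sac3d1 (2.32), Gss (2.20), 102812_i_at (2.14), Msh3 (2.09), Gnb1 (2.08), Dio2 (1.86), Hopx (1.85), Ilvbl (1.83), Mrps25 (1.80), Ank1 (1.75) and Cox6a2 (1.74). Hopx, a homeodomain protein, had -1.63 in males and 0.22 in females, and the protease Klk6 -3.16 and -0.46. Itgav, Abcc3 and Msh3 owed more to females, with 2.57, 1.70 and 1.94 there and -0.64, -0.85 and -0.15 in males. Single mice moved some of these by over 1.5 times: Itgav was 1.41 without wild-type 3 and 4.999 without wild-type 5, and without null 2 Abcc3 was 1.56 and Ilvbl 1.14. The 15 largest negative ones were Vamp1 (-5.11), Rangap1 (-4.39), Nfyc (-3.92), Mark2 (-3.86), Ssr3 (-3.86), Capn1 (-3.65), Rgs4 (-3.52), Commd5 (-3.51), 96606_at (-3.48), Kif1b (-3.46), 93909_f_at (-3.45), Actb (-3.45), Rex1bd (-3.36), Fmod (-3.32) and Emc8 (-3.29); 96606_at was -2.08 without wild-type 5. Ssr3, a subunit of the translocon-associated complex, had 25.5 ± 12.5 (SD, n = 4) in wild-type males and 441.4 ± 73.3 (SD, n = 2) in null males, and Rgs4, a regulator of G protein signalling, 15.6 ± 8.41 (SD, n = 4) and 177 ± 9.83 (SD, n = 2). Other probe sets of some of these genes did not share the direction or the size. The male difference was 1.19 for Gnb1 through 94854_g_at. The interaction was 0.87 for Mark2 through 99458_i_at and, of the same sign but near 0, -0.05 for Ssr3 through 96007_at. For Rangap1 98602_at gave an interaction of -1.43 (limma adjusted p = 0.0463). The 3′ and 5′ Actb control probe sets disagreed, with null minus wild-type differences in males of -0.65 and 1.04 log2.

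**Figure D5:**
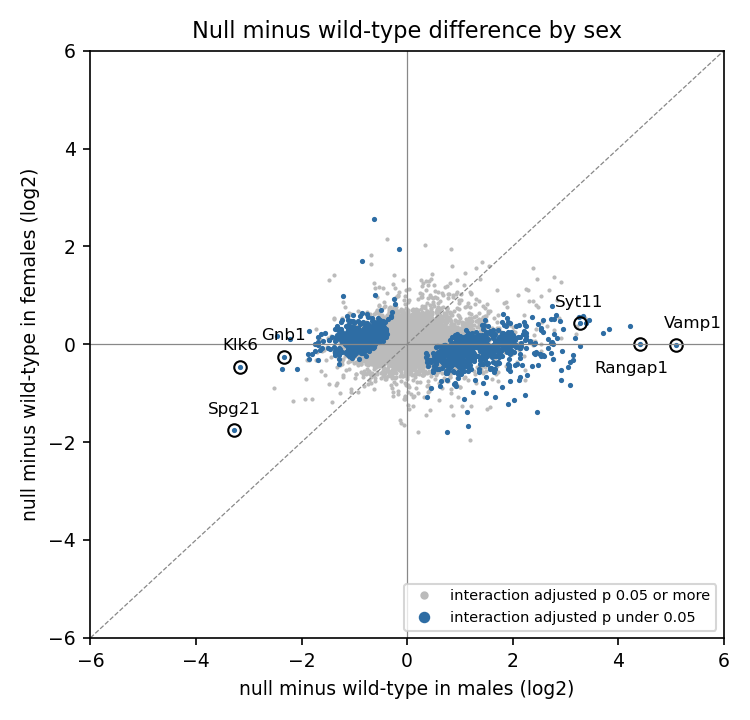
Null minus wild-type log2 difference in females against that in males for each tested probe set; blue marks an interaction past the adjusted threshold, and circles mark named genes. Vamp1 (5.10) and Rangap1 (4.41) lie far to the right with female differences near 0, while Spg21 lies at -3.28 in males and -1.76 in females.

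Synaptic vesicle genes rose as a list in males (20 genes, median 0.73, camera adjusted p = 0.0342; with an estimated correlation adjusted p = 0.821), where 10 passed higher over all genes, among them Vamp1 (5.10), Syt11 (3.27), Syt1 (2.74) and Cplx1 (2.15), and 2 lower, Pclo (-0.91) and Dnm1 (-0.86). Mitochondrial respiratory chain genes fell as a list in males (36 genes, median -0.47, camera adjusted p = 0.00996; with an estimated correlation adjusted p = 0.835). Of these 20 passed lower, with Ndufa5 (-1.36), Ndufc1 (-1.11) and Uqcrc2 (-1.10) at the head, and 5 higher, Uqcrc1 (1.73), Ndufv1 (1.35), Ndufa9 (1.13), Sdha (1.03) and Ndufs3 (0.51). Both lists passed for the interaction too, synaptic vesicle genes downward (adjusted p = 0.0207, 9 of 20 negative and 2 positive) and the respiratory chain upward (adjusted p = 0.00501, 14 of 36 positive and 4 negative); with an estimated correlation each had an adjusted p of 0.743. Fry called 6 lists in males and 4 for the interaction, the other 26 lists did not pass with camera, though oligodendrocyte genes did for the interaction with age as a covariate (adjusted p = 0.0416), and 0 passed in females. The male null brains had the lowest Gapdh control ratios, 0.859 and 0.798. Their difference also had a trend with signal, given below, in which dimmer probe sets rose against brighter ones. The list tests did not remove this trend. Respiratory chain genes lower in males included bright ones, as Cox6a1 (6664.8 in wild-type brains), and dim ones, as Atp5k (121). Quantile normalization ended the calls of the respiratory chain (camera adjusted p = 0.382 in males and 0.214 for the interaction).

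Scaling set the balance of higher and lower calls in males. Centring each array on its median moved the median difference of all probe sets in males from 0.05 to -0.23, and the male calls were then 765 higher and 2004 lower, 27.6% higher against 54.7% as deposited. Quantile normalization moved that median to -0.08, with 1119 higher and 1425 lower (44.0% higher). The interaction calls under median centring were 892 positive and 414 negative, 68.3% positive against 45.5% as deposited, with the median of all probe sets at 0.20 instead of -0.02. For genotype and sex, median centring moved the median of all probe sets to -0.15 and 0.17. The median of all probe sets stood at 0.05 in males as deposited. Against that median, synaptic vesicle genes in males stayed higher and respiratory chain genes lower under each of the 3 scalings (medians 0.73, 0.73 and 0.44, and -0.47, -0.33 and -0.75). Median centring moves all probe sets of an array by the same amount, so it could not change this. Only quantile normalization could, and under it the respiratory chain list no longer passed in males.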

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

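The within-gene comparison of probe sets, the count of male null arrays inside the wild-type Gapdh range and the Gapdh covariate were tests chosen only after the result was seen.

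The null minus wild-type difference was not the same in males and females, by a test of the interaction itself. The male difference rests on 2 null brains with Gapdh 3′/5′ ratios of 0.859 and 0.798. Sex and these 2 arrays therefore cannot be told apart. The interaction of genotype and sex passed for 1187 probe sets (limma). Among them the positive values, where the female difference lay above the male one, included the integrin Itgav at 3.21, the protease Klk6 at 2.70, the sterol synthesis kinase Mvk at 2.64, the transporter Abcc3 at 2.55, Sac3d1 at 2.32, the glutathione synthetase Gss at 2.20, 102812_i_at at 2.14, the mismatch repair gene Msh3 at 2.09, the G protein subunit Gnb1 at 2.08 and the deiodinase Dio2 at 1.86. Hopx followed at 1.85, Ilvbl at 1.83, Mrps25 at 1.80, Ank1 at 1.75 and Cox6a2 at 1.74. Negative values were those of the vesicle gene Vamp1 at -5.11, the Ran activator Rangap1 at -4.39, Nfyc at -3.92, the kinase Mark2 at -3.86, Ssr3 at -3.86, the calpain Capn1 at -3.65, Rgs4 at -3.52, Commd5 at -3.51, 96606_at at -3.48, the kinesin Kif1b at -3.46, 93909_f_at at -3.45, Actb at -3.45, Rex1bd at -3.36, Fmod at -3.32 and Emc8 at -3.29. Without wild-type 3 Itgav stood at 1.41 and without wild-type 5 at 4.999, without null 2 Abcc3 stood at 1.56 and Ilvbl at 1.14, and without wild-type 5 96606_at stood at -2.08. Without null 2, null 1 or wild-type 5 the count was 461, 650 or 499. Leaving out a male null or a female wild-type mouse leaves 1 of its kind, which is then assumed to vary like the other groups.

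All male effects rest on 2 null brains, whose arrays had Gapdh 3′/5′ ratios of 0.859 and 0.798. The scaling of the arrays is argued against as the cause, since 1356 probe sets passed after quantile normalization. Labelled RNA reaching further from the 3′ end is a candidate explanation for part of the pattern. Within 926 genes with several probe sets, the dimmest lay above the brightest in the male difference by a median of 0.30 log2. Once the trend of that difference with signal was removed, the median was 0.129 (quartiles -0.51 and 0.69, sign-flip permutation p = 0.0006). In females it was -0.01 after the same removal. The sign flips treat genes of the same arrays as independent, so this p does not measure the spread between mice. Probe positions were not used, so a dim probe set is only assumed to lie further from the 3′ end. The slope on the Gapdh ratio in the other 9 arrays tracked the male difference at only r = 0.0567 across probe sets, which are not independent (exact permutation p = 0.215, one-sided). With the ratio as a covariate 0 interactions passed (limma; 659 at an unadjusted p under 0.05), partly because errors grew, as for Gnb1 from 2.08 (SE 0.23) to 2.10 (SE 0.55), and partly because differences shrank, as for Rangap1 from -4.39 (SE 0.55) to -1.90 (SE 1.01). An effect of the null genotype in males stays open and cannot be told apart from that of the RNA. The reason is that 0 of the 2 male null arrays had a ratio inside the wild-type range of 3.57 to 5.92. The scaled signal of the spiked-in bacterial transcript BioC also set them apart, at 370.6 and 377.7 against 535.9 to 783 on the other 9 arrays. A spiked-in transcript does not come from the mouse, so these 2 arrays differed in more than the RNA of single mouse genes.

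For each comparison 100 splits of the arrays into groups of the same sizes were counted, the real one included, and splits for the interaction were drawn within each sex. For the interaction 2 splits, the real one among them, gave at least the real 1187. For genotype 3 gave at least the real count of 2, but splits that part the 2 male null arrays called 0 and so could not reach it. For sex the count says nothing about chance, since the real count was 0 and all 100 splits must reach it. The highest counts of other splits were 605 for genotype, 574 for sex and 1338 for the interaction, which points to a structure of the samples. Every split in these draws that called any probe set put the 2 male null arrays together, and the highest count with them apart was 0. Of the other splits with them together, 2 of 47 reached the real count for genotype and 1 of 46 for the interaction. Splits counted as together could have both arrays in the wild-type group, unlike the real one. Chance was therefore not excluded for genotype or for the interaction.

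The 5′ Gapdh control probe set, which was not among the probe sets tested for genotype and served only in the Gapdh ratio, had a mean signal of 7051.5 ± 898.7 (SD, n = 2) in male null brains, above the 1340.4 ± 297 (SD, n = 6) of wild-type and the 2053.7 ± 520.5 (SD, n = 3) of female null brains. Between male groups the 3′ and 5′ control probe sets differed by 0.19 and 2.58 log2 for Gapdh, by -0.65 and 1.04 for Actb, by 0.84 and 1.63 for Pcx and by 2.22 and 2.64 for Tfrc. The wild-type 3 brain lay far below the other wild-type brains for Spg21, at a signal of 211.6 against 426.8 to 534.2. The wild-type 4 brain had a Gapdh 3′/5′ ratio of 5.92, far above the other wild-type brains. These were 2 of 50 groups of values tested for a sample far from the others, and chance alone would give about 2.5.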

How the results depend on the processing

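Leaving out the 2 male null arrays, the same within B4 animals, the Gapdh 5′/3′ ratio as a covariate, B4 animals alone for sex and the interaction, the lists on the interaction and within each sex, and the lists after median centring were tests chosen only after the data were seen; the other alternatives were planned. No paired analysis was run because replicate numbers pair no mice and the labels, which call the controls littermates, do not say which mice share a litter. The alternatives for Chrnb4 gave no value, since it has no probe set. Apart from smaller sets of mice, genes or neighbours, whose construction changes what can pass, the cause was not tested.

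Of 2 probe sets called for genotype, 1 passed after quantile normalization, median centring, with the filter at the 60th percentile or without a covariate. By limma 0 passed without the filter (2102 at an unadjusted p under 0.05), with age (847), in females only (390), without the male null arrays (264) and with the Gapdh covariate (347). In B4 animals 26 passed (24 higher), in males only 1984 (1101 higher), with array weights 1741 (998 higher), at an adjusted p of 0.10 275 (183 higher), and in B4 animals without the male null arrays 1, Itgav, named after its value was seen. Leaving out 1 mouse gave 1 to 877, with 877 without wild-type 5, 195 without wild-type 3, 9 without null 5 and 1 otherwise. Another floor, no trend and the number letters as a block gave 2 or 3.

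For sex, 0 probe sets passed (limma, 926 at an unadjusted p under 0.05), but 2 did with the floor at the 25th percentile, 3 without the filter, 10 in B4 animals and 1232 with array weights (564 higher in females). Leaving out 1 mouse gave 0, except for 30 without wild-type 5. For the interaction 1187 became 644 in B4 animals and 0 with the Gapdh covariate (limma, 659 at an unadjusted p under 0.05), and lay between 930 and 1763 under the other alternatives. Leaving out 1 mouse gave 461 (without null 2) to 1406 (without wild-type 2), with 650 without null 1 and 499 without wild-type 5.

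The odds ratio of calls near Chrnb4 went from 0 to 4.12 in B4 animals (exact Fisher p = 0.226), 3.39 at an adjusted p of 0.10 (p = 0.00459), 41.8 for 250 genes on each side (p = 0.0465) and 17.99 for the whole chromosome (p = 0.103). Leaving out 1 mouse gave 0 to 3.43, with 3.43 without wild-type 3 (exact Fisher p = 0.012) and 1.39 without wild-type 5. It had no finite value without the filter, with age, in females only, without the male null arrays or with the Gapdh covariate, where nothing was called.

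Of the gene lists 0 passed for genotype, but 2 did after quantile normalization and 1 after median centring, with age, with the number letters as a block, in B4 animals and without wild-type 5 (0 to 1 over all mice left out). For sex 2 passed, but 0 with the estimated correlation, fry or the male null arrays left out, 4 with age, 1 with the Gapdh covariate, and 1 (without wild-type 5) to 3 (without wild-type 2 or 3) with 1 mouse left out. For the interaction 2 passed, but 0 with the estimated correlation, 4 with fry, 1 after quantile normalization, 1 with the Gapdh covariate, and 1 (without wild-type 3) to 2 with 1 mouse left out. With the estimated correlation 0 of the 84 camera calls of these comparisons, over the settings tried for lists, held (lowest adjusted p = 0.32).

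The 146 log2 differences of named genes had 3005 alternative values. For genotype 1234 kept direction and side of the threshold, 87 moved past it, 20 lost it and 45 changed sign; for sex these were 784, 13, 16 and 27, and for the interaction 670, 2, 107 and 0. None of the differences that changed sign had passed over all genes. Without the male null arrays the genotype differences turned to 0.11 for Chrna6, -0.14 for Chrna7, -0.084 for Chrne 92965_at, 0.20 for Chrne 92966_g_at, -0.29 for Cplx1 and -0.0091 for Vamp1. With the Gapdh covariate they turned to 0.41 for Chrna6, -0.091 for Chrna7, 0.091 for Chrnb1, 0.26 for Chrnd, -0.21 for Chrne 92965_at, 0.49 for Chrne 92966_g_at, -0.078 for Gabrd, -0.15 for Stx1a, -0.65 for Cplx1, -0.24 for Nsf, -0.12 for Syp, -0.44 for Vamp1 and -0.068 for Nptx1. In B4 animals without the male null arrays they were 0.44 for Chrna6, -0.47 for Chrna7, 0.26 for Chrnb1, 0.065 for Chrnd, -0.90 for Chrne 92965_at, 0.30 for Chrne 92966_g_at, -0.022 for Chrne 92967_r_at, -0.15 for Gabra2, 0.0024 for Gabrb1, -0.089 for Slc1a1, -0.015 for Syt3, -0.032 for Glul and -0.028 for Nptx1. Chrna7 and Chrnb2 turned to -0.059 and -0.072 after quantile normalization and to -0.063 and -0.085 after median centring, Chrna7 to -0.055 without a covariate, and Chrnb2 to -0.0016 with the floor at the 25th percentile.

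Sex differences that changed sign were those of Ddx3x 101542_f_at after median centring (0.12), of Ddx3x 101542_f_at and Bdnf with age (0.10 and -0.0035), and, without the male null arrays, of Ddx3x 101542_f_at (0.47), Ddx3x 93309_at (0.81), Kdm5d (0.34), Bdnf (-0.46), Klf4 (-0.26), Sgk1 (-0.11), Ndufv1 (0.32), Sdha (0.25) and Uqcrc2 (-0.28). With the Gapdh covariate they were 0.26 for Ddx3x 101542_f_at, 0.41 for Ddx3x 93309_at, -0.23 for Bdnf, -0.073 for Klf4, 0.13 for Ndufv1, 0.090 for Sdha and -0.088 for Uqcrc2. With 1 mouse left out the genotype differences ran from -0.25 to 0.061 for Chrna6, -0.74 to 0.052 for Chrnb1, -0.13 to 0.33 for Chrnb2 and -0.20 to 0.075 for Chrne 92966_g_at. Those of sex ran from -0.042 to 0.42 for Bdnf, -0.26 to 0.068 for Ddx3x 101542_f_at, -0.76 to 0.14 for Ddx3x 161273_f_at, -0.52 to 0.041 for Ddx3x 93309_at and -0.0088 to 0.32 for Klf4. Of the nicotinic subunits only Chrna7, Chrng 95639_at and Chrne 92967_r_at exceeded the filter, a signal of 25.8, and folds near the floor of 3.1 are understated.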

Other observations

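The tests of LT against B4 arrays, of chance placement and of strain DNA were chosen only after the result was seen; that with the Gapdh covariate was written before its result.

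Wild-type brains from mice with LT numbers differed from wild-type brains with B4 numbers, with genotype and sex in the model. The autophagy gene Map1lc3a had a signal of 987.8 ± 115 (SD, n = 3) in LT and 367.7 ± 127 (SD, n = 3) in B4 wild-type brains (1.48 log2). Icam5, an adhesion molecule of forebrain dendrites, had 888 ± 93.4 (SD, n = 3) and 365.9 ± 140 (SD, n = 3; 1.34). Psd, an exchange factor found at synapses, had 0.83, the disulphide isomerase Pdia3 1.07, the prostaglandin enzyme Ptges2 1.01, the glycosyltransferase A4galt 1.81, the GTPases Rala and Rnd2 1.48 and 2.37, the G protein subunit Gnaz 1.56 and the tetraspanin Tspan5 2.04. S100a5, a calcium-binding protein of olfactory neurons, was lower in LT brains, at 42.6 ± 13.2 (SD, n = 3) against 171.7 ± 54.3 (SD, n = 3; -2.02), and 92812_f_at at -2.14 was the only other probe set lower. In all 35 passed (limma), 33 of them higher in LT brains.

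A batch of array processing is a candidate explanation for the LT difference, because the lowest ratio of the spiked-in transcripts BioB to BioC among LT arrays was 1.77 times the highest among B4 arrays. Null brains, all with B4 numbers, lay nearer to B4 than to LT wild-type brains in mean log2 signal for 24 of the 35 probe sets and nearer to LT for 11. Among the 11 were Gnaz (mean signal 123.3 in null and 108.9 in LT brains) and Rnd2 (196.9 and 210.2). The null means include the male null brains, whose arrays stood apart, so these values do not decide for or against a batch. The LT mice are all wild-type and 6 weeks old, younger than the B4 mice, so batch and age cannot be told apart. No biological explanation was tested, and what the letters stand for is not stated in the sources used here.

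In the 9 brains without the male null brains, more genes near Chrnb4 than elsewhere had an unadjusted p under 0.05, though no single gene passed (limma; 264 of all probe sets had an unadjusted p under 0.05). Those within 100 genes at an unadjusted p under 0.05 were the serotonin receptor subunit Htr3a (-1.55), Pts (-1.18), the respiratory chain subunit Sdhd (-0.97), Dlat (-0.68), Cryab (-0.67), Myo9a (-0.52), the glucokinase Adpgk (-0.52) and the smooth muscle protein Tagln (0.69). With sex in the model this difference rests on 3 null against 2 wild-type females, and 1 of these, wild-type 5, has an LT number. In males the differences were -1.42 for Pts, -1.21 for Cryab, -1.15 for Adpgk, -0.50 for Dlat and 0.57 for Tagln, but -0.13 for Htr3a, 0.03 for Sdhd and 0.09 for Myo9a. Spg21, 123 genes away, had -1.76 in the 9 brains.

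These 8 of 63 genes are 12.7%, and 0 of 4270 other windows of as many consecutive tested genes held as large a share. The highest was 11.1% on chromosome 5. These windows overlap, and the subset of brains was chosen after the data were seen. With the male null brains included there was no excess, at 20.6% against 22.8% of other genes, but so high a background could hide a few genes. Because of the overlap and the late choice of brains, chance placement is not excluded. DNA of another strain kept around the targeted gene stays an open hypothesis: the share beyond 250 genes on chromosome 9 was lower, 4.79% or 8 of 167 (exact Fisher p = 0.0446), but the genes closest to Chrnb4, where such DNA would lie first, showed no excess, with 0 of 12 within 25 positions and 1 of 26 (3.85%) within 50. With the Gapdh 5′/3′ ratio as a covariate in the same 9 brains, the share was 6.35% within 100 genes against 3.72% of other genes (exact Fisher p = 0.299), so strain DNA and the difference in that ratio between genotypes cannot be told apart. An effect of the missing subunit on these genes was not tested and stays open.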
